A study of Zea mays with 18 samples.

How the data were processed

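RNA sequencing of maize anthers gave 18 libraries, 3 for each of 3 stages and 2 genotypes. The deposited count tables, 1 per stage, hold raw counts per gene that the authors did not normalise. The 18 deposited tables per library, laid out as StringTie gene abundance tables, give TPM (transcript abundance scaled by the authors to each library) and, per the file headers, coverage, a signal of mean read depth per base of a gene. Bowtie2, StringTie and DESeq2 were used per the submitters' processing notes. Their versions and settings, the genome build, strand counting, and the treatment of reads that map to several genes or paralogs are not given in the sources used here.

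All tests used the raw counts. Groups followed the stage and genotype in the labels, and the tables list 45578 genes: 43789 with a Zm00001d identifier, 154 microRNA precursors and 1635 others. Replicate columns of the count tables were checked against the coverage of the samples over 19610 genes, and 18 of 18 matched their own sample best, with r from 0.955 to 0.988.

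Genes with low counts were left out with filterByExpr of edgeR 4.0.16 (R 4.3.3), with a minimum count of 10 and a minimum total of 15. This kept 24694 genes, with 99.9% of the counts, and left out 20884. Libraries were scaled by TMM, with factors from 0.845 to 0.854 in S3-4 ZmCCT(+) and from 0.961 to 1.08 in the others. The quasi-likelihood F test of edgeR (robust) was run on 1 fit of all libraries with 6 groups and 12 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes with an adjusted p below 0.05 were called. There were 9 comparisons: genotype at each stage, its average over stages, its interaction with stage, and each stage step in each genotype. CPM values are scaled by TMM and given as mean and SD of 3 libraries. Errors of log2 fold changes are SE, computed as the absolute log2 fold change over the square root of the quasi-likelihood F.

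Genes named for a genotype comparison were chosen by a rule fixed before the data were examined. In the absence of gene names it left the 2 highest and 2 lowest log2 fold changes among called genes without a name that had a mean of at least 1 CPM and no overlap between genotypes. zma-MIR168a at S3-4 and zma-MIR2275c at S5-6, S7 and on average met the rule as genes with a name. The other microRNA values, genes of the silent stretches and genes seen in only one genotype are named by later choice, after their values were seen. Of the identifiers, 153 microRNA precursors matched the gene table used here, which belongs to assembly Zm-B73-REFERENCE-NAM-5.0, and 0 of 43789 Zm00001d identifiers did. Of 29 gene lists fixed beforehand, 0 had a matched member, so no list was tested.

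Total counts ran from 14846974 to 23652182 per library. A group with no count was set to a floor of 3 counts over its 3 libraries, between 0.0470 and 0.0642 CPM, and folds against it are lower bounds. With 1 to 3 counts, the ratio has an exact Clopper-Pearson interval at 95%. Intervals and floors cover counting error only. All 18 pairs of replicates differed beyond counting noise, with chi-square over degrees of freedom from 1.58 to 3.14. The coefficient of variation between replicates was 3.20% over all groups and 4.08% in S3-4 ZmCCT(+).

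Genes were called silent in a group at 3 counts or fewer over its libraries and expressed at 10 or more in each. Clusters of such genes were tested by 10000 random draws of as many genes, and 1-Mb windows by a hypergeometric test. Counts were simulated with the estimated spread and the same mean level in every group. Only genes above a minimum mean count were changed, in S7 ZmCCT(+) alone. Of these, 97 of 100 changed 2-fold and 54 of 100 changed 1.25-fold were recovered, and 9 of 24494 unchanged genes were called. With so few genes changed, the simulation did not test scaling between groups that differ in most genes.

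Alternatives planned before the data were examined were DESeq2 1.42.0 size factors and test, limma-voom and limma-trend on TPM (limma 3.58.1, pseudocounts 1 and 0.1), no filter, a stricter filter, a replicate block, only the libraries compared, an adjusted p below 0.01 for the interaction, a 2-fold minimum and leaving out each library. An assumed spread of 20% and leaving out all S3-4 libraries were added after seeing the data. The assumed spread was used with edgeR's likelihood ratio test in place of the quasi-likelihood F test, so both spread and test change.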

Results

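RNA was sequenced from maize anthers of plants carrying an active ZmCCT10 transgene, here ZmCCT(+), and of non-transgenic control plants, here ZmCCT(-). ZmCCT10 is a CCT-domain regulator known for delaying flowering of maize in long days. Anthers were taken in 3 developmental windows that the labels call S3-4, S5-6 and S7, with 3 libraries for each stage and genotype, 18 in all. The series asks how the anther transcriptome differs between the genotypes over these stages. The deposited count tables listed 45578 genes, and the total count per library ran from 14846974 to 23652182. Each library had counts for between 28018 and 29256 genes. The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values below measure only the spread between these libraries, which may be technical.

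The transgenic S3-4 anthers had an expression profile far from that of every other group. The first principal component of the 1000 most variable genes held 62.1% of the variance and ran from the 3 S3-4 ZmCCT(+) libraries, at scores of 106, 108 and 107, to the remaining 15, which lay between -44.3 and 16.7. Log2 CPM, the count scaled to library size, of an S3-4 ZmCCT(+) library correlated at Pearson's r between 0.839 and 0.843 with the S3-4 controls across genes, and at 0.756 to 0.763 with S5-6 ZmCCT(+). Libraries of one group correlated at 0.991 to 0.994. Control stages differed far less from each other, with r from 0.948 between S3-4 and S7 up to 0.986 between S5-6 and S7. The 10 most abundant genes took 3.67% to 3.93% of the counts in S3-4 ZmCCT(+) and 1.75% to 2.10% in the other libraries.

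**Figure D1:**
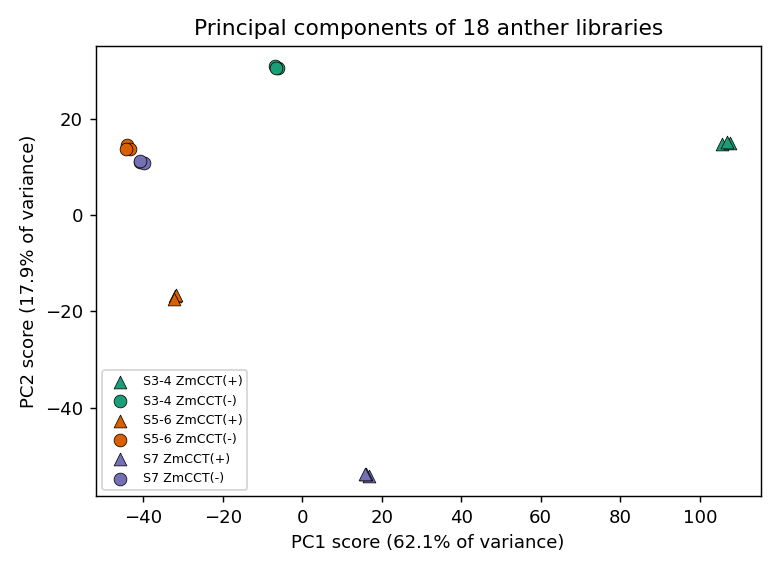
Scores of the 18 libraries on the first and second principal components of log2 CPM of the 1000 most variable genes, with colour for stage, circles for ZmCCT(-) and triangles for ZmCCT(+). The S3-4 ZmCCT(+) libraries stand alone at scores of 106 to 108 on the first component, and S5-6 and S7 ZmCCT(-) lie close together.

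ZmCCT10 itself, which would check the genotype labels, was not analysed here by name, because the deposited tables list maize genes by identifiers that neither they nor the gene table used here pair with names. Maize genes are therefore given by identifier, by microRNA name where the identifier is one, by chromosomal region or by their behaviour across groups. Coordinates are those of the deposited tables, whose genome build is not given in the sources used here.

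At S3-4 the genotypes differed in the levels of most genes. Of 24694 genes tested, 4767 were at least 2-fold higher and 5156 at least 2-fold lower in ZmCCT(+) at an adjusted p below 0.05 in edgeR's quasi-likelihood test, and 1134 and 729 of these differed by 8-fold or more. Zm00001d009054 (chromosome 8, 33466268 to 33469138) had 75.8 ± 3.33 CPM (SD, n = 3) in ZmCCT(+) and no count in ZmCCT(-), at least 1331-fold higher against a floor of 3 counts over the 3 control libraries (edgeR adjusted p = 3.27e-61). Zm00001d047323 (chromosome 9, 126607955 to 126611605) had 59.2 ± 0.924 CPM and again no control count, at least 1038-fold higher (edgeR adjusted p = 1.70e-59). Zm00001d002136 (chromosome 2, 6496902 to 6497840) fell from 2.01 ± 0.654 CPM in the control to no count, at least 31.7-fold lower (edgeR adjusted p = 2.55e-15). Zm00001d049480 (chromosome 4, 31734764 to 31741600) fell from 11.97 ± 0.663 to 0.0642 ± 0.0662 CPM, a ratio of 186 with a 95% exact counting interval of 63.5 to 906 (edgeR adjusted p = 2.26e-43).

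Among the 7 microRNA precursors with enough counts to test, 5 differed at S3-4. The zma-MIR168a precursor, whose microRNA targets ARGONAUTE1 transcripts, was 6.02-fold higher (log2 2.59 ± 0.21 SE, edgeR adjusted p = 1.14e-19), at 6.78 ± 0.339 CPM (SD, n = 3) against 1.12 ± 0.165. zma-MIR156d was 6.62-fold higher (log2 2.73 ± 0.61 SE, edgeR adjusted p = 3.83e-05), while zma-MIR156j went the other way, with 1 count in ZmCCT(+) and 17 in ZmCCT(-), a ratio of 15.1 with a 95% counting interval of 2.36 to 631 (edgeR adjusted p = 0.00179). The fold of zma-MIR156d rests on 37 counts in ZmCCT(+) and 6 in ZmCCT(-). MicroRNAs of the miR156 family target SPL transcription factors. zma-MIR2275b and zma-MIR2275c belong to the family that triggers phased small RNAs in meiotic anthers. Neither had a count in S3-4 ZmCCT(+), against 31 and 6 counts in the controls, so they were at least 9.17-fold and 1.78-fold lower (edgeR adjusted p = 5.29e-07 and 0.00768). zma-MIR2275b, at 31734063 to 31734144 on chromosome 4, lies close to Zm00001d049480, which was also lower at S3-4. These 2 losses may therefore not be separate. zma-MIR2118c and zma-MIR2118e, of the family that triggers phased small RNAs before meiosis, had log2 fold changes of 0.79 and -0.03 that did not pass (edgeR adjusted p = 0.108 and 0.938); without ZmCCT(-) replicate 1 zma-MIR2118c passed (adjusted p = 0.0273).

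Without a fold minimum 20068 genes passed at S3-4, 9973 higher and 10095 lower. The estimated coefficient of variation between replicates was only 3.20%, so small differences pass. With an assumed 20% and edgeR's likelihood ratio test, a setting chosen after seeing the data, 14469 passed. Limma-trend on log2(TPM + 1) gave 8902 higher and 11231 lower, and on log2(TPM + 0.1), where the median of all genes moved by -0.12, 8887 and 11330. With a 2-fold minimum these settings gave 3428 higher and 4497 lower, then 4183 and 5633. Directions are relative to the TMM scaling, which takes most genes as unchanged, while 81.3% of tested genes were called here.

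At S5-6 the difference between genotypes was smaller, and more of the strong changes were losses. Genes at least 2-fold higher in ZmCCT(+) numbered 1348 and those at least 2-fold lower 1720; beyond 8-fold the numbers were 90 and 261. The 2-fold numbers were 734 and 1097 with the stricter low-count filter, which keeps 19276 genes, and 787 and 1071 with limma-trend on log2(TPM + 1). The highest were Zm00001d004649 (chromosome 2, 125603869 to 125605944), at 44.5 ± 3.24 CPM (SD, n = 3) against no control count, at least 874-fold (edgeR adjusted p = 1.74e-24), and its neighbour Zm00001d004644 (chromosome 2, 124805300 to 124818947), at 25.99 ± 0.710 CPM against none, at least 510-fold (edgeR adjusted p = 1.96e-49). Zm00001d003690 (chromosome 2, 54515841 to 54521636) had 27.0 ± 1.246 CPM in the control and no count in ZmCCT(+), at least 572-fold lower (edgeR adjusted p = 3.68e-54), although it was at 20.1 ± 0.0982 CPM in ZmCCT(+) at S3-4 and 29.3 ± 2.09 at S7. Zm00001d053618 (chromosome 4, 236692389 to 236693329) had 2309 counts in the control and 1 in ZmCCT(+), a ratio of 2509 with a 95% counting interval of 450 to 99145 (edgeR adjusted p = 1.57e-52). zma-MIR2275c was 6.22-fold lower (log2 -2.64 ± 0.12 SE, edgeR adjusted p = 4.47e-34), at 3.24 ± 0.215 CPM against 20.2 ± 2.24, and none of the other 6 precursors passed. Without a fold minimum 15594 genes passed, 7351 higher and 8243 lower, but limma-trend on log2(TPM + 1) gave 7828 higher and 7250 lower, and with a pseudocount of 0.1 it gave 7612 and 7128. With the assumed spread of 20%, 5471 genes passed.

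At S7, transgenic anthers again had more strong losses than gains. There were 792 genes at least 2-fold higher and 1415 at least 2-fold lower, or 476 and 712 with the stricter filter, and 183 and 252 beyond 8-fold. Zm00001d008904 (chromosome 8, 24559394 to 24563053) reached 65.0 ± 2.39 CPM (SD, n = 3) against no control count, at least 1208-fold (edgeR adjusted p = 3.20e-60), and Zm00001d009054 reached 60.8 ± 2.07 CPM against none, at least 1132-fold (edgeR adjusted p = 2.07e-58). Both were also high at S3-4 and near or at 0 in S5-6 ZmCCT(+), with 2 counts and none. Zm00001d044461 (chromosome 3, 228815712 to 228816647) and Zm00001d044470 (chromosome 3, 229091994 to 229098812) had no count in S7 ZmCCT(+) against 71.0 ± 1.09 and 67.3 ± 4.11 CPM in the control, at least 1285-fold and 1222-fold lower (edgeR adjusted p = 5.79e-68 and 6.93e-65). zma-MIR2275c was 47.3-fold lower (log2 -5.56 ± 0.18 SE, edgeR adjusted p = 5.53e-44), at 0.457 ± 0.0808 CPM against 22.2 ± 1.02. zma-MIR168a was 1.37-fold higher (log2 0.46 ± 0.17 SE, edgeR adjusted p = 0.0184), but not without ZmCCT(-) replicate 1 or 3 (adjusted p = 0.0781 and 0.0514) or ZmCCT(+) replicate 2 or 3 (0.0666 and 0.130, all from edgeR), nor with the assumed spread of 20% (0.323). Without a fold minimum 13449 genes passed, 44.3% of them higher in ZmCCT(+). DESeq2 size factors gave 48.2% higher, the stricter filter 49.9% and only the libraries compared 49.8%. Tested as log2(TPM + 1) with limma-trend, 64.4% of calls were higher and the median of all genes moved by 0.13. That setting changes test, unit and scaling together. The direction of small changes at S7 therefore depends on the processing. DESeq2 size factors, the only setting that changed scaling alone, moved the median of all genes by 0.025 and did not turn it. Whether scaling turned it with TPM was not tested. Losses of 2-fold or more still outnumbered gains with limma-trend, at 667 against 488. With the assumed spread of 20%, 3280 genes passed.

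**Figure D2:**
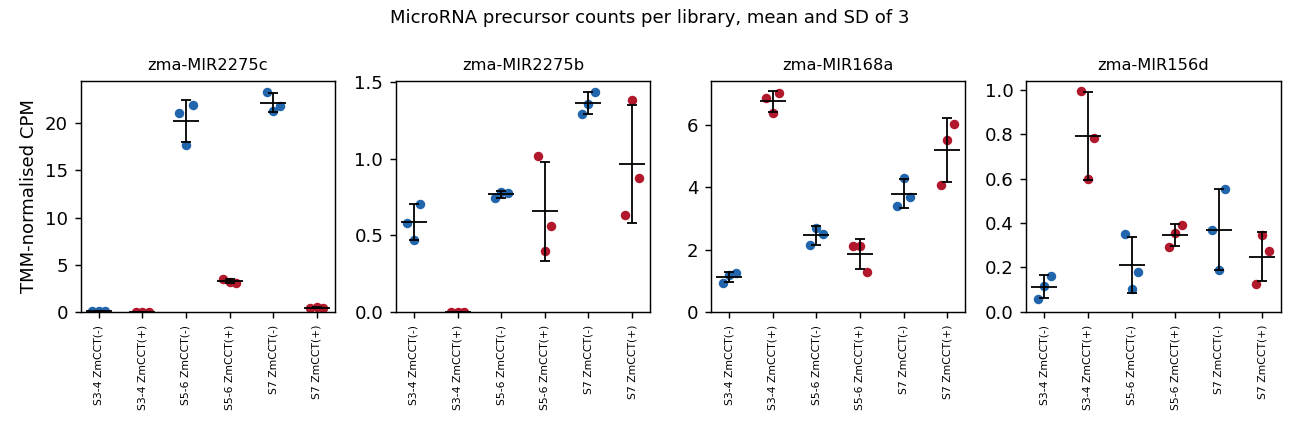
TMM-normalised CPM of 4 microRNA precursors in each library (points, blue for ZmCCT(-) and red for ZmCCT(+)), with the mean and SD of the 3 libraries of each group. zma-MIR2275c averages 20.2 and 22.2 CPM in the S5-6 and S7 controls and 3.24 and 0.457 CPM in ZmCCT(+).

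**Figure D3:**
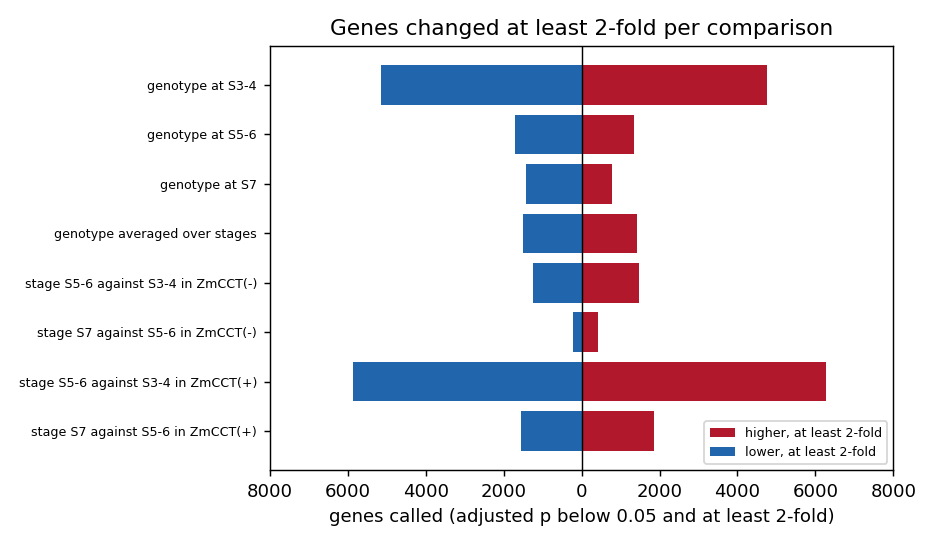
Number of genes with an adjusted p below 0.05 and at least a 2-fold change in each comparison, those higher to the right of 0 (red) and those lower to the left (blue). The genotype comparison at S3-4 and the step from S3-4 to S5-6 in ZmCCT(+), which share the S3-4 ZmCCT(+) libraries, have the most genes, 9923 and 12142.

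Averaged over the 3 stages, 1431 genes were at least 2-fold higher and 1497 at least 2-fold lower in ZmCCT(+). The stricter filter gave 843 and 913, and which side was larger depended on the method, with 1475 and 1432 by DESeq2 size factors, 1550 and 1480 by the DESeq2 test and 1510 each by limma-voom. Zm00001d004644 and Zm00001d004649, with counts in each ZmCCT(+) library and in no control, led the gains, at 25.7 and 28.0 CPM over the 9 transgenic libraries. Both lie in a stretch of chromosome 2, described below, where all 7 expressed genes had almost no control counts. A segment missing or divergent from the reference in control plants and an effect of the transgene were not told apart there. The lowest were Zm00001d039648 (chromosome 3, 10362846 to 10363205), at 4.22, 9.99 and 0 CPM over the stages in ZmCCT(+) against 21.3, 28.7 and 30.6 in ZmCCT(-), and Zm00001d044470, at 16.5, 54.3 and 0 CPM against 82.2, 69.9 and 67.3. All 4 had edgeR adjusted p-values of 1.19e-27 or lower. Without a fold minimum 18600 genes passed; this average leaned on S3-4, since without the S3-4 libraries 14636 passed, 480 of them at least 2-fold higher and 1095 at least 2-fold lower, and 2644 genes called both ways had the opposite sign. With the assumed spread of 20%, 11181 passed.

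The effect of genotype differed between stages for most genes. The test of the interaction called 21376 of 24694 genes, 15077 without the S3-4 libraries and 13646 with the assumed spread. Genotype effects at different stages share no library, so their overlap can be counted. Of the 1717 genes called and changed at least 2-fold at both S3-4 and S5-6, 49.3% went the same way, while 80.5% of 1428 did so between S3-4 and S7 and 73.6% of 924 between S5-6 and S7. At all 3 stages 148 genes were at least 2-fold higher and 157 at least 2-fold lower; independent lists would give 8.35 and 20.6. The edgeR and limma-voom interaction tests differed for zma-MIR2118c, with adjusted p of 0.0517 and 0.0232. The edgeR interaction test is not usable for genes with no count in several groups. This applied to Zm00001d009054 (4 groups) and to Zm00001d047323, Zm00001d053618, Zm00001d004649 and Zm00001d004644 (3 groups each). Limma-voom gave adjusted p-values of 4.35e-13, 1.46e-12 and 2.85e-10 for the first 3 of them and did not call the last 2 (0.136 and 0.501).

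In control anthers the main change fell between S3-4 and S5-6. In that step 1477 genes rose and 1250 fell by at least 2-fold, compared with 427 and 210 from S5-6 to S7. With the stricter filter the numbers were 714 and 849, then 155 and 73, so the balance of the first step depends on genes with few counts, and with the assumed spread 275 and 141 were left in the second. zma-MIR2275c rose 167-fold from S3-4 to S5-6 (log2 7.39 ± 0.23 SE, edgeR adjusted p = 7.65e-45), from 0.114 ± 0.00529 to 20.2 ± 2.24 CPM (SD, n = 3), and the next step did not pass (log2 0.13). Its S3-4 level rests on 6 counts, 2 in each library, so the SD of 0.00529 is below counting error and the fold is uncertain. zma-MIR168a rose in both steps, by 2.17-fold and 1.57-fold (edgeR adjusted p = 4.56e-05 and 0.00352), though the second rise did not pass with the assumed spread (0.317), and zma-MIR2118e fell 2.17-fold in the first (edgeR adjusted p = 0.00152). zma-MIR2275b rose 1.77-fold in the second (edgeR adjusted p = 0.0452), but not without any 1 of the 9 control libraries (up to 0.115) or with the assumed spread (0.289). The call was also lost in edgeR with a replicate block (0.0522), DESeq2 size factors (0.0504) or no filter (0.0730), and by the DESeq2 test (0.112). Without a fold minimum 13897 and 10462 genes passed, and with the assumed spread of 20% 4022 and 559.

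In transgenic anthers both steps involved more genes. From S3-4 to S5-6, 6271 genes rose and 5871 fell by at least 2-fold, and from S5-6 to S7 1846 rose and 1556 fell, or 1272 and 887 with the stricter filter. All 7 precursors passed in the first step. zma-MIR2275c had no count at S3-4 and rose at least 50.5-fold by S5-6 (edgeR adjusted p = 4.04e-24), then fell 6.94-fold by S7 (log2 -2.80 ± 0.25 SE, edgeR adjusted p = 3.53e-17), a step that did not pass in the controls. zma-MIR2275b rose at least 10-fold between S3-4 and S5-6 (edgeR adjusted p = 1.10e-07). zma-MIR168a fell 3.59-fold and then rose 2.78-fold (edgeR adjusted p = 1.62e-15 and 5.76e-11). zma-MIR2118c and zma-MIR2118e fell 4.43-fold and 2.72-fold in the first step (edgeR adjusted p = 0.000185 and 4.69e-05). zma-MIR2118e then rose 1.93-fold (edgeR adjusted p = 0.0118), but not without S5-6 replicate 1 or S7 replicate 2 (0.0508 and 0.0693), and the rise of zma-MIR2118c did not pass (0.0564), though it did by limma-voom (0.0295) and without S5-6 replicate 3 or S7 replicate 2 (0.0365 and 0.0276). The first-step fall of zma-MIR156d (2.27-fold, edgeR adjusted p = 0.0156) was not called without S3-4 or S5-6 replicate 1 (0.0834 and 0.0526), nor the rise of zma-MIR156j from 1 count to 14 (0.0111) without S3-4 replicate 3 (0.0536). Without a fold minimum 21202 and 15716 genes passed, and with the assumed spread 16773 and 5954.

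Genes that change over control development were compared with the genotype effect at a stage whose libraries do not enter that control change. Of the 1477 genes that rose at least 2-fold from S3-4 to S5-6 in controls, 878 were lower and 95 higher in ZmCCT(+) at S7, or 59.4% lower against 30.4% of all tested genes. Of the 1250 that fell in that step, 537 were lower and 248 higher at S7, or 43.0% lower, so both sets were more often lower than all tested genes. At S5-6, of 1313 genes that fell at least 2-fold from S3-4 to S7 in controls, 686 were lower and 194 higher in ZmCCT(+), and of 2262 that rose, 939 were higher and 603 lower. That is 52.2% lower and 14.8% higher, then 41.5% higher and 26.7% lower. Of all tested genes 29.8% were higher and 33.4% lower at S5-6. At S3-4, 228 of the 427 genes that rose from S5-6 to S7 in controls were higher and 83 lower, and of the 210 that fell, 56 were higher and 60 lower. That is 53.4% higher and 19.4% lower, then 26.7% higher and 28.6% lower. Of all tested genes 40.4% were higher and 40.9% lower at S3-4, so the genes that fell lay below both shares. Across the genes past the threshold for the control change, Pearson's r between control change and genotype effect was 0.224 at S3-4 (Spearman's rho 0.213, 10462 genes), 0.0399 at S5-6 (rho 0.355, 15984 genes) and -0.350 at S7 (rho -0.249, 13897 genes). These correlations are across genes, which are not independent replicates.

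A small set of genes was silent in whole groups and expressed in others. Of 35439 genes that either had at least 10 counts in each library of a group or at most 3 counts over the group, in all 6 groups, 142 changed state between groups. The state differed between ZmCCT(+) stages for 120 of them and between ZmCCT(-) stages for 16. In ZmCCT(+), 33 genes were silent at S7 alone, 28 at S3-4 alone and 13 at S5-6 alone, while each was expressed in the other 5 groups. A further 20 were expressed in S3-4 ZmCCT(+) alone, 16 in S3-4 and S7 ZmCCT(+) alone and 8 in ZmCCT(+) at all 3 stages, and 11 in ZmCCT(-) at S5-6 and S7 alone. Of the 33, 16 and 8 genes, 19, 4 and 7 had another of their class within 1 Mb (permutation test, adjusted p = 0.00035, 0.021 and 0.00035), while 2 of the 20 did (0.35) and none of the 28, 13 and 11.

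**Figure D4:**
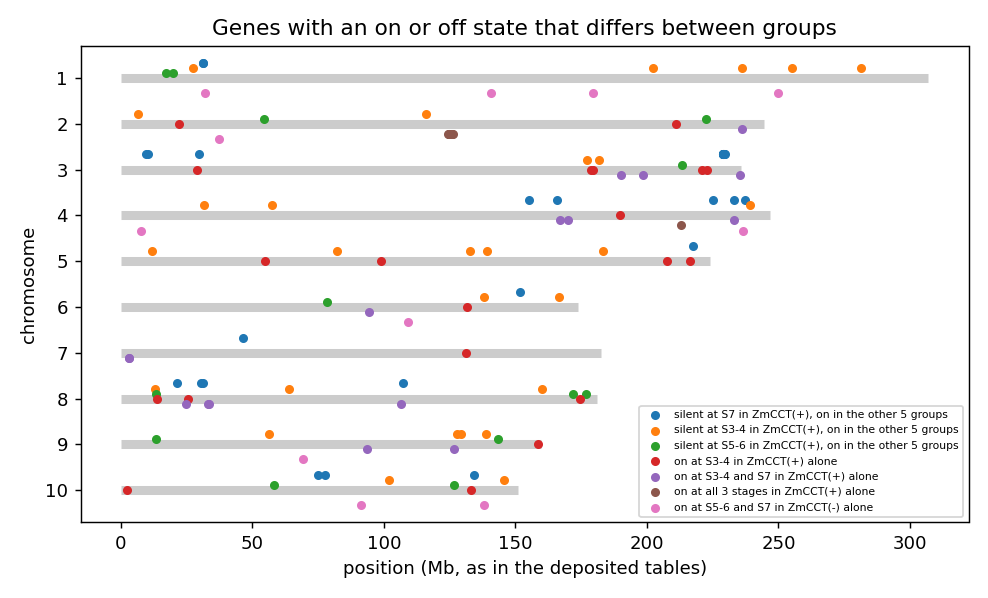
Start positions, in Mb, of genes whose expressed or silent state differed between groups, on the 10 chromosomes (grey bars to the last gene), with colour for the groups concerned, classes of at least 5 genes shown and points set off vertically by class. Of the 33 genes silent at S7 in ZmCCT(+) (blue), 13 lie together on chromosome 3, and 7 of the 8 expressed at all 3 stages in ZmCCT(+) alone (brown) lie together on chromosome 2.

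On chromosome 2, between 124419556 and 126280335, all 7 genes with at least 50 counts in either genotype had counts in ZmCCT(+) and almost none in ZmCCT(-). Over the 14 gene models of this stretch of 1.86 Mb, ZmCCT(+) had 21325 counts and ZmCCT(-) 16, or 0.0750%. Another 2 genes in it had few counts, and both had more in ZmCCT(-), 10 against 2 and 2 against 0. The nearest expressed gene to the right, starting at 126652987, had 4429 counts in ZmCCT(+) and 4478 in ZmCCT(-). The nearest to the left, starting at 122503563, had 203 and 33. Over 10 flanking expressed genes and the 3 stages the median absolute log2 fold change was 0.49 and the largest 3.85. At S3-4 the left flanking genes were all higher in ZmCCT(+), with log2 fold changes from 0.51 to 3.85. On chromosome 3, between 228815712 and 229578470, 13 of 14 genes with at least 50 control counts had at most 3 counts in S7 ZmCCT(+); the 13 genes had 4 counts together against 23154 in S7 ZmCCT(-). The remaining gene, from 229247796 to 229256127, was just above that limit, at 0.0753 CPM against 78.8 in S7 ZmCCT(-). In S5-6 ZmCCT(+) the same 13 genes stood at a median of 99.7% of the control level (73.5% to 197%), and in S3-4 ZmCCT(+) at 30.8% (4.70% to 57.7%). A scan of 1-Mb windows for genes changed 8-fold or more found both places among 8 windows that passed. At S7, 8 of 17 and 6 of 18 tested genes of the windows from 229000001 and 228000001 on chromosome 3 were lower (hypergeometric test, Benjamini-Hochberg adjusted p = 4.34e-09 and 1.64e-05 over 1837 windows). All 4 genes of the window from 124000001 on chromosome 2 were higher at S5-6 and S7 (adjusted p = 3.03e-07 and 5.36e-06), as were 3 of 5 genes of the window from 33000001 on chromosome 8 at S7 (adjusted p = 0.00364). The other 3 windows, on chromosomes 4, 5 and 10 at S5-6, had 3 changed genes each (adjusted p = 0.0101, 0.00695 and 0.0419). No window passed at S3-4, where 1134 genes were higher and 729 lower by 8-fold or more.

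**Figure D5:**
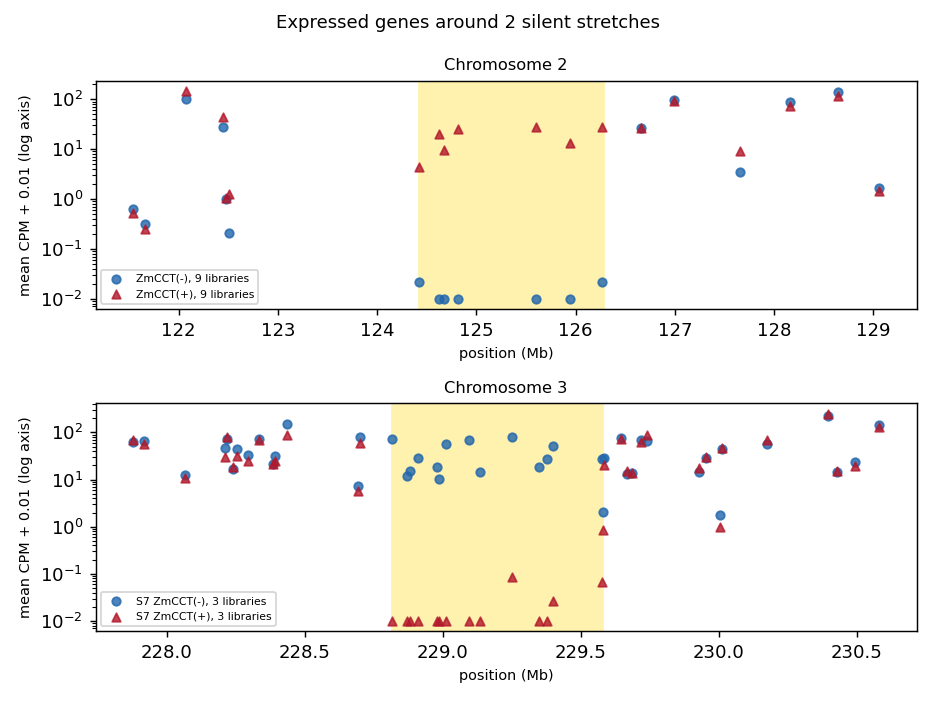
Mean CPM plus 0.01 on a log axis against position in Mb for expressed genes around the silent stretches (yellow), for 9 libraries of each genotype on chromosome 2 and for the 3 S7 libraries of each genotype on chromosome 3. All 7 plotted genes of the stretch on chromosome 2 lie at or near the floor in ZmCCT(-), and all 14 on chromosome 3 do so in S7 ZmCCT(+), at 0.0753 CPM or less.

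Counting only genes with counts in all 9 libraries of one genotype and none in the 9 of the other, 7 were found in ZmCCT(+) and 1 in ZmCCT(-). Of the 7, 5 lie in the chromosome 2 stretch. The others were on chromosome 3 (1447428 to 1449364), with 1138 counts, 1030 of them at S3-4, and on chromosome 10 (94430850 to 94433495), with 34 counts in all and between 1 and 10 per library. The gene seen only in ZmCCT(-) lies on chromosome 7 (2272477 to 2273904) and had 71 counts over 9 libraries. No count in 9 libraries allows a level of up to 0.0180 CPM in ZmCCT(-) and 0.0182 CPM in ZmCCT(+), from counting error alone.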

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

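The tests of neighbouring genes, chromosome 3 levels, abundant genes, library correlations, dilution and replicate spread were chosen after the results were seen, and the counts of other splits were planned before. The genotype effect differed between stages for 21376 of 24694 genes by the edgeR interaction test. Among the named genes this held for Zm00001d002136 (adjusted p = 7.34e-12), Zm00001d003690 (3.89e-51), Zm00001d008904 (0.00206), Zm00001d039648 (3.75e-34), Zm00001d044461 (9.96e-63), Zm00001d044470 (2.14e-58) and Zm00001d049480 (7.96e-37). It also held for zma-MIR156d (0.0019), zma-MIR168a (8.11e-15), zma-MIR2275b (4.83e-05) and zma-MIR2275c (3.70e-16). zma-MIR2118c passed by limma-voom (adjusted p = 0.0232) and not by edgeR (0.0517). Zm00001d009054, Zm00001d047323 and Zm00001d053618 passed by limma-voom (adjusted p = 4.35e-13, 1.46e-12 and 2.85e-10). The edgeR interaction test is not usable for these 3 genes, which had no count in 4, 3 and 3 groups.

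Some of the genes silent in whole groups lay in runs. Of the 33 genes silent at S7 in ZmCCT(+) alone, 19 had another within 1 Mb, against at most 10 in 10000 random draws (permutation p = 1e-04, the smallest they can give), which argues against chance placement. Other genes within 1 Mb of any of the 33 were called with a 2-fold change at S7 in 16.1% of cases against 8.66% elsewhere. Segments missing or divergent from the reference in some plants may account for this. The share was not computed for the runs alone, and it counts the near-silent gene from 229247796 inside the chromosome 3 run. Beside that run, the expressed genes from 228697874, 229578773 and 229584377 stood at 60.9, 0.823 and 20.1 CPM in S7 ZmCCT(+), against 81.3, 2.07 and 28.5 in S7 ZmCCT(-). Whether such segments account for the runs was therefore not decided. The 13 genes of the chromosome 3 run stood at a median of 99.7% of the control level in S5-6 ZmCCT(+). They were selected as silent at S7 alone and expressed in the other 5 groups. Their S5-6 level therefore shows only that these genes were not switched alike at every stage. It cannot test whether ZmCCT10 activity switches other genes alike. The state differed between ZmCCT(+) stages for 120 genes and between ZmCCT(-) stages for 16; switching that differs between stages and a different background of the plants cannot be told apart, since the labels do not give the background at each stage.

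The S3-4 ZmCCT(+) libraries stood apart. Their 10 most abundant genes held at most 3.93% of the counts of a library, while a 2-fold fall of the other genes would need 50%. This argues against a 2-fold fall of the others from a few genes taking counts. It does not test the low r, since an even fall would hardly change r across genes. Their highest r with any control library was 0.843, below the lowest r between control stages, 0.948, which argues against control-like anthers of an age between S3-4 and S7. Of 11395 genes with at least 20 CPM in the control, 265 were at least 8-fold lower, and dilution would need 87.5% of other material for that, so a minor share of other tissue is argued against. A large share of other tissue and anthers younger than S3-4 or older than S7 stay open and were not tested. The same holds for a different background of the plants and an effect of the transgene.

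Replicates differed little, with a coefficient of variation of 3.20% beyond counting error. Repeat libraries of 1 RNA pool and separate samples cannot be told apart from this, since the labels do not give the origin of replicates. With an assumed 20% the interaction would have 13646 genes.

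Other splits of the libraries were counted for all 9 comparisons. For the average, 1 of 100 splits, the real one, gave as many as 18600 genes (highest other 13203), and for the interaction 1 of 100 gave as many as 21376 (highest other 17059). Splits that mix the closely alike replicates of both genotypes widen the spread within a group, so fewer calls are largely built in. The splits therefore cannot exclude chance differences between plants or RNA pools. For the 7 comparisons of 3 libraries with 3, 1 of 10 splits, the real one, gave as many genes, which is too few splits for a share under 0.05. Their real counts were 20068, 15594 and 13449 for genotype at S3-4, S5-6 and S7, 13897 and 10462 for the steps in ZmCCT(-) and 21202 and 15716 in ZmCCT(+). The highest other split gave 1 gene at S7 and 0 in the other 6.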

How the results depend on the processing

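The assumed spread of 20% and leaving out the S3-4 libraries were chosen after seeing the data. Called genes without a fold minimum stayed within 1.5 times the reported number in all 9 comparisons without any 1 library, and under the other settings except the following. With a 2-fold minimum there were 9923, 3068 and 2207 genes for genotype at S3-4, S5-6 and S7, 2928 for the average, 2727 and 637 for the steps in ZmCCT(-) and 12142 and 3402 in ZmCCT(+), since this asks for more. These 2-fold numbers moved by more than 1.5 times with the stricter filter (higher and lower, 734 and 1097 at S5-6, 476 and 712 at S7, 843 and 913 for the average, 714 and 849, then 155 and 73 for the steps in ZmCCT(-), 1272 and 887 for the second step in ZmCCT(+)), with limma-trend on log2(TPM + 1) at S5-6 (787 and 1071) and S7 (488 and 667), with the assumed spread in the second ZmCCT(-) step (275 and 141) and without the S3-4 libraries for the average (480 and 1095). The average had more genes higher than lower by DESeq2 size factors (1475 and 1432) and the DESeq2 test (1550 and 1480). With the assumed spread there were 5471 at S5-6, 3280 at S7, 11181 for the average, 13646 for the interaction, 4022 and 559 for the steps in ZmCCT(-) and 5954 for the second step in ZmCCT(+), since it is wider than the estimate. Replicate numbers did not pair libraries (r from -0.248 to 0.101), and with them as a block 20040, 15574 and 13427 genes passed for genotype at the 3 stages. Over all tested genes the correlation with control development was 0.155 at S3-4 and -0.258 at S7, and without 1 library it lay between -0.351 and -0.348 at S7. The first principal component of all tested genes held 61.1%. Of 1812 recomputed values of named genes, 1764 kept direction and call, 29 lost the call, 7 gained it and 12 changed sign; the cause was not tested. Without 1 library, log2 fold changes of zma-MIR2118e ranged from -0.29 to 0.23 at S3-4, -0.024 to 0.48 at S7 and -0.17 to 0.032 on average. Those of zma-MIR2275b ranged from -0.71 to 0.058 at S5-6, and of zma-MIR2118c from -0.62 to 0.029 at S7. For the steps in ZmCCT(-), those of zma-MIR2118c ranged from -0.51 to 0.26 in the first and of zma-MIR156j from -0.22 to 0.89 in the second. The second ZmCCT(-) rise of zma-MIR2275b was lost in 16 of its recomputations. Without the S3-4 libraries the averages of zma-MIR168a (log2 0.07, edgeR adjusted p = 0.681) and zma-MIR2275b (-0.33, 0.252) were not called. zma-MIR156j passed at S5-6 without ZmCCT(-) replicate 2 (0.0380) and at S7 without ZmCCT(-) replicate 3 (0.0235). Alternatives for the gene lists and the transgene were not run, as no list had a matched member and the transgene was not analysed by name. Depth limits precursors with few counts, such as zma-MIR2275c at S3-4 with 6 counts in 3 control libraries.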

Other observations

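The tests of clustering for each class of silent or expressed genes were chosen after the results were seen. Of the 8 genes expressed in ZmCCT(+) at all stages and silent in ZmCCT(-), 7 had another within 1 Mb, against at most 4 in 10000 random draws (permutation p = 1e-04, the smallest they can give; Benjamini-Hochberg adjusted p = 0.00035 over 7 classes). Of the 16 expressed in S3-4 and S7 ZmCCT(+) alone, 4 had one (permutation adjusted p = 0.021). None of the 28 genes silent at S3-4 in ZmCCT(+) alone or of the 13 silent at S5-6 alone had one.

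The correlation of genotype effect with control development was set against 10 splits of the libraries of a stage. The size of r was 0.350 at S7 against 0.316 for the highest other split, 0.224 against 0.247 at S3-4 and 0.0399 against 0.0443 at S5-6. Other splits keep part of the genotype difference, and 10 splits are too few for a share under 0.05.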
